A study of Bradyrhizobium diazoefficiens USDA 110 with 24 samples.

How the data were processed

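Messenger RNA levels of the soil bacterium Bradyrhizobium diazoefficiens, named Bradyrhizobium japonicum in the design text, and of an ntrC mutant of it were compared on 24 arrays with 2 channels each. Per the labels, total RNA was extracted with hot phenol, copied into cDNA with random hexamers and labelled with Cy3 or Cy5. Cells were free-living and grew on minimal medium with 10 mM glutamate (low nitrogen) or with 10 mM glutamate and 10 mM ammonium (high nitrogen). Each of the 4 comparisons had 3 biological replicates, and each replicate was hybridised on a forward array and on an array with the dyes exchanged.

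The deposited values are log2 ratios of the channels of 1 array, already normalised by the authors, for 8480 probes. The base of the logarithm is not stated and was read as 2, because the extremes would make base 10 implausible. Column medians ran from -0.0311 to 0.00887, so the columns were used as deposited. How background, spot quality and dye effects were treated before deposit is not given in the sources used here. The files hold no intensities, so no probe could be called present or absent. Dye-swap columns were found to be turned to the sign of the forward columns already. Forward and dye-swap means of a comparison correlated across genes at 0.687 to 0.83. Of genes picked for a change of at least 4-fold on the forward arrays alone, 30 of 30, 6 of 6, 32 of 32 and 23 of 23 had the same sign in the dye-swap mean. In unturned columns a dye bias common to all arrays would make the comparisons run the same way. The wild type response and the strain comparison in high nitrogen were instead opposed across genes as deposited (0.498 after the strain ratios were turned, as follows). The wild type response and the strain comparison in low nitrogen ran the same way as deposited (-0.268 after turning), so that pair does not argue against such a bias.

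The forward titles name the mutant first in the strain comparisons, but the values ran the other way and were multiplied by -1 to give mutant over wild type. This direction is likely rather than stated. The design text names the wild type first, and the loop of the 4 comparisons closed with a median absolute deviation of 0.07 over genes in this reading, against 0.35 in the titled one. The dye bias of genes, taken as forward minus dye-swap value over 8095 genes, correlated across genes at 0.705 to 0.768 between nitrogen and strain comparisons in this reading and at -0.768 to -0.705 in the titled one. These checks leave open whether all 4 comparisons should be turned together; the nitrogen ratios were kept as titled.

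The platform annotation listed 8462 of the 8480 probes, each with 1 symbol, and 1469 probes had a symbol other than their locus tag. The reference gene table of assembly ASM164267v1 does not link to the locus tags of the array, so symbols are those of the platform and no coordinates or product names were used. Probes of the same gene were averaged on each array, which left 8269 genes, 191 of them with several probes. A gene needed a value in at least 2 of 3 replicates of every comparison, which 7836 genes met and 433 did not. Per array, 7930 to 8461 probes had a value. The number of arrays limits the precision.

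The forward and dye-swap values of a replicate were averaged, and the 12 averages were fitted with limma (version 3.58.1, R 4.3.3) as 4 group means with a shared estimate of the spread. Each mean was tested against 0 with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The interaction, the difference between the nitrogen responses of the strains, was the average of its estimates from the nitrogen and the strain comparisons. The loop closure, which is 0 for a gene if the comparisons measured the same 4 conditions, was tested in the same fit. Overlaps of called genes were tested with Fisher's exact test and correlations between comparisons were set beside 20 simulations of unchanged genes with shared RNA. The p-values of this fit measure the spread between these replicates, taken as independent between comparisons, and do not extend to other strains or cultures.

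The labels give the same replicate numbers to every comparison without saying what they share. Deviations from the group means correlated at 0.853 to 0.978 in all 18 pairs of same-numbered replicates of different comparisons and at -0.532 to -0.427 between different numbers, over 7516 genes. The replicate number removed 95% of the spread around the group means. The fit without the block takes the deviations of different comparisons as independent. Its p-values therefore rest on fewer independent deviations than its 8 residual degrees of freedom assume, and for the comparisons they can be too small. By this check same-numbered replicates share deviations, on the basis of the values and not of the labels, which does not show that they share cultures or RNA. Array by array, however, the deviations of a forward array from its comparison mean correlated at a median of 0.414 with its own dye swap and, of the dye swaps of the other numbers, at -0.976 to -0.911 with the most opposed and at 0.25 to 0.402 with the remaining one. Neither the replicate number nor the dye orientation alone sets these signs, so what a replicate number stands for stays open. The model chosen before the data were examined has no replicate block, so its values are given first, with those of a fit with the replicate number as a block beside them for the counts of genes and for the lists described. With the block, deviations shared by same-numbered replicates leave the error, so its p-values and counts do not measure the spread between replicates. For example, bll7538 stood at -1.22 ± 0.81 in mutant over wild type in low nitrogen. Its adjusted p from limma went from 0.345 to 1.17e-08 with the block.

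Gene lists were fixed before the data were examined: nitrogen regulation and ammonium assimilation, nitrate assimilation, urea and purine nitrogen sources (members found were 6 urease genes), nitrogenase genes with fixABCX, microaerobic fix genes, denitrification, flagella and chemotaxis by symbol, a pair of flagellar clusters by locus tag, nodulation and type III secretion, ribosomal proteins, respiratory chain with ATP synthase, hydrogenase with carbon fixation, chaperones, and exopolysaccharide with polyhydroxybutyrate. These 15 lists had members on the array. A further 2, amino acid and peptide transport and transposases, depended on product names and had none. Each list was tested against the other genes with camera of limma at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. Members called were counted over all genes and adjusted over the list alone.

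Named genes followed a rule fixed before the data were examined. The ntrC probe came first. In each comparison the 10 largest rises and the 10 largest falls were taken among called genes with 1 sign in all 3 replicates, and in the interaction by the adjusted p alone. All members of the nitrogen regulation and nitrate lists could be named, and of every other list up to 4 called members, or 1 if none was called. Genes outside this rule were chosen after their values were seen and are given as such.

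The steps were tested on simulated data with 7516 genes. For a nitrogen response in the wild type, the fit without the block recovered 2.94% of 68 genes changed by 0.5 on the log2 scale, 43.9% of 66 changed by 1 and 97% of 66 changed by 2, with 0 false calls. With the block it recovered 92.6%, 100% and 100%, with 0 false calls. The simulated deviations of the replicate numbers summed to 0 within every comparison and so added no error to its mean. The 0 false calls therefore do not test for calls caused by such error, which the block would leave out of its estimate. None of 10 unchanged lists passed, with or without the block.

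Alternatives covered centring, scaling, each replicate left out, each comparison fitted alone, robust and unmoderated variances, all 24 arrays with a dye term and a random block, a single dye orientation, stricter and looser filters, the median over probes, a 2-fold minimum, a loop fit of the 4 conditions, single routes to the interaction, and the replicate block. The block for the comparisons, the overlap and the lists, its combination with the 2-fold minimum, and the titled direction were chosen after seeing the data.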

Results

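Transcript levels were compared on 24 arrays in a loop of 4 comparisons, each with 3 biological replicates and 6 arrays. They were wild type and ntrC mutant in low over high nitrogen, and mutant over wild type in low and in high nitrogen. Per array, 7930 to 8461 of 8480 probes had a value. Values are log2 ratios given as mean ± SD over replicates, n = 3 unless stated, and adjusted p-values are from limma. Strain ratios are given as mutant over wild type, which is opposite to the direction of the forward titles. That reading is likely on the basis of the order in the design text, the closure of the loop and the dye bias. Genes named as higher or lower in a comparison had the same sign in every replicate with a value.

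The ntrC probe (blr4488), the gene removed in the mutant by its name, gave values that followed the dye orientation. In low over high nitrogen in the wild type its mean was 1.80 ± 0.58 on forward arrays and -0.34 ± 0.77 on dye-swap arrays. In mutant over wild type it was 0.05 ± 1.05 and -1.13 ± 0.64 in low nitrogen, and 1.63 ± 0.58 and -0.27 ± 0.24 in high nitrogen. Its forward minus dye-swap difference of 1.74 lay at the 99.9th percentile of all genes by size. It was not called in any of the 4 comparisons, with adjusted p of 0.355 in the nitrogen response of the wild type and 0.984 and 0.76 in low and high nitrogen between strains. In low over high nitrogen in the mutant it was 0.29 ± 0.38 and -1.42 ± 0.26 (adjusted p = 0.804). With the replicate block the wild type response of the probe passed, at adjusted p = 0.0378, as did its interaction of -1.26, at 0.00365 against 0.0698 without the block. Averaged over both orientations, mutant over wild type was -0.54 ± 0.84 in low nitrogen and 0.68 ± 0.23 in high nitrogen, so the probe was not lower in the mutant in high nitrogen. The part of the gene that was removed is not stated.

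The nitrogen response of the wild type asks which genes change when ammonium is withheld and glutamate is the nitrogen source. The largest rise was that of blr1448, by 5.68 ± 0.13 (51.1-fold, adjusted p = 1.5e-08). Among genes of ammonium assimilation, glnK (blr0612), a PII signalling protein, rose by 4.66 ± 1.31 (25.3-fold), glnII (blr4169), glutamine synthetase II, by 3.73 ± 0.44 (13.2-fold), and amtB (blr0613), an ammonium transporter, by 2.44 ± 0.61 (5.42-fold). Among genes with a value in all 3 replicates the largest falls were in bkdA1 (blr6331), a subunit of the branched-chain 2-oxo acid dehydrogenase, at -4.80 ± 0.48, and in bll6809, at -4.43 ± 0.44.

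Of 16 members of the nitrogen regulation list 6 rose and 0 fell. Besides glnK, glnII and amtB these were the second glnK (blr0606), at 1.80 ± 0.30, glnB (blr4948), another PII protein, at 1.58 ± 0.19, and nifR (blr4486) at 1.12 ± 0.50. Adjusted over the list alone, 6 rose and 1 fell, and with the replicate block 10 rose and 3 fell. The list ranked above the other genes (adjusted p = 7.44e-08), a call lost at adjusted p = 0.0998 with an estimated correlation. Of 10 nitrate assimilation genes 2 rose, and 4 adjusted over the list alone. They were nrtA (blr2803), which binds nitrate for transport, at 2.73 ± 0.51, and bll4571 at 2.61 ± 0.55. The list ranked higher (adjusted p = 2.63e-05; adjusted p = 0.14 with an estimated correlation), and with the block 6 members rose and 1 fell.

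Other named rises were bll6154 at 2.85 ± 0.25, bll5738 at 2.68 ± 0.23, bll3763 at 2.55 ± 0.80 and bll6424 at 2.40 ± 0.53. Among 6 urease genes ureB (blr1455), for a subunit of the enzyme, rose by 1.16 ± 0.23. Of 34 nodulation and type III secretion genes 3 rose, rhcC2 (bll1842) by 0.76 ± 0.18, rhcJ (blr1813) by 0.55 ± 0.12 and rhcU (blr1822) by 0.54 ± 0.11. This list ranked higher (adjusted p = 0.000756; adjusted p = 0.0998 with an estimated correlation), and with the block 18 members rose and 2 fell. The denitrification gene nosF (blr0317) rose by 0.82 ± 0.10, and cheWII (blr2344), a chemotaxis protein, by 0.98 ± 0.39. The flagella and chemotaxis list by symbol did not pass (adjusted p = 0.264; 24 of 61 higher and 12 lower with the block), nor did the flagellar cluster around fliC (adjusted p = 0.191; 3 higher and 10 lower with the block), in which blr6846 fell, at -0.81 ± 0.36. The denitrification list did not pass either (adjusted p = 0.264; 6 of 16 higher and 1 lower with the block), nor the urease list (adjusted p = 0.102; 4 of 6 higher and 1 lower with the block).

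Among the falls, bkdA2 (blr6332), of the same dehydrogenase, stood at -2.10 ± 0.63. asd (blr4687), aspartate-semialdehyde dehydrogenase, fell, at -3.46 ± 0.70 and metX (blr1399), homoserine O-acetyltransferase, at -2.38 ± 1.02. The neighbouring genes blr5962, blr5963 and blr5966 stood at -3.77 ± 0.89, -3.04 ± 1.20 and -3.00 ± 0.85, and bll5338 and bll6807 at -3.41 ± 0.26 and -2.19 ± 0.61. Of 41 respiratory genes 3 fell, all of succinate dehydrogenase, sdhA (blr0514) at -2.07 ± 0.58, sdhB (blr0515) at -1.82 ± 0.46 and sdhD (blr0513) at -1.68 ± 0.13. In the same list cyoC (blr0151), of a quinol oxidase, rose by 0.77 ± 0.39. The list as a whole did not pass (adjusted p = 0.202; 6 higher and 14 lower with the block). Of 52 ribosomal protein genes 0 were called, at a median of -0.19, and the list ranked lower (adjusted p = 0.00157; adjusted p = 0.14 with an estimated correlation). With the block 9 of them rose and 35 fell.

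Of 7836 genes 220 passed, 106 higher and 114 lower in low nitrogen. With the replicate block 4085 passed, 1930 higher and 2155 lower. All 220 were among them with the same sign, and 154 passed the block with at least a 2-fold change. Without replicate 1 of this comparison 76 genes passed, and without replicate 3 99 did. The chaperone list (26 genes, median 0.08) passed with the block alone, at adjusted p = 0.0331 against 0.191, with 10 members higher and 3 lower (adjusted p = 0.279 with the block and an estimated correlation).

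**Figure D1:**
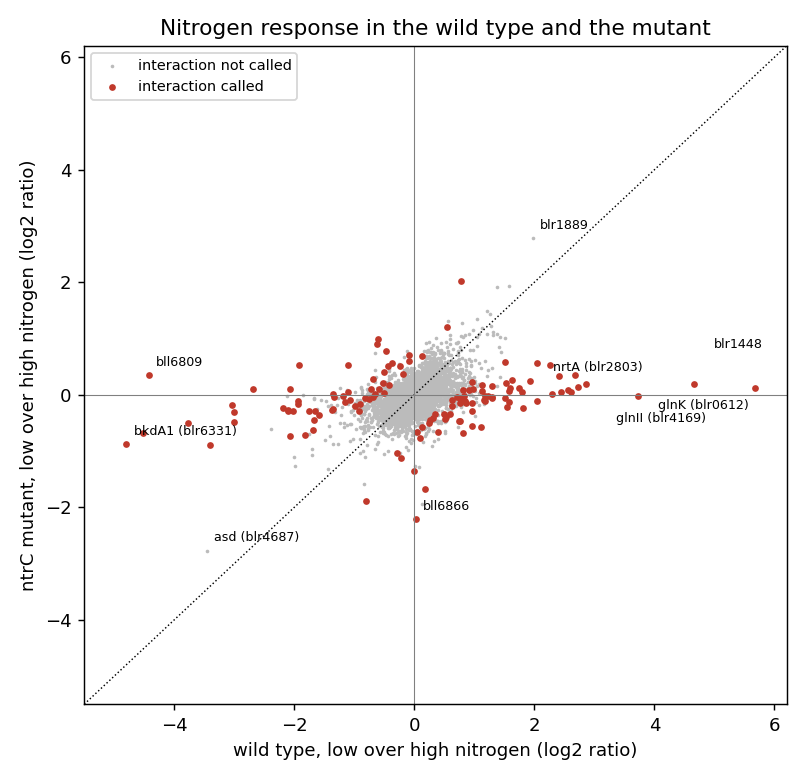
Log2 ratio of low over high nitrogen in the wild type (x axis) against the ntrC mutant (y axis), 1 point per gene, with the 132 genes called in the interaction in red. blr1448 and glnK (blr0612) lie far to the right near 0 on the y axis, while blr1889 and asd (blr4687) lie nearer the dotted line of equal response. Their interaction of 0.81 each passed limma's test with the block alone. The adjusted p was 4.85e-05 against 0.0608 for blr1889 and 0.0011 against 0.394 for asd.

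The nitrogen response of the mutant asks what remains of the response without NtrC, a response regulator of nitrogen metabolism. blr1889 rose by 2.78 ± 0.26 (6.87-fold, adjusted p = 8.39e-05), with its neighbours blr1891 at 1.92 ± 0.36 and blr1890 at 1.49 ± 0.22. asd (blr4687) had the largest fall, at -2.77 ± 0.76. Flagellar genes fell in the cluster around fliC (bll6855), a flagellin gene. bll6866 stood at -2.21 ± 0.23, blr6846 at -1.89 ± 0.06 and flgD (bll6853), for the assembly of the flagellar hook, at -1.67 ± 0.50.

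Of the 39 measured genes of that cluster 6 fell and 0 rose, and 16 fell adjusted over the list alone. bll6847 stood at -1.36 ± 0.27, fliC at -1.12 ± 0.24 and flgL (bll6856), of the hook-filament junction, at -1.04 ± 0.23. The cluster ranked below the other genes (adjusted p = 2.8e-20, or 0.00224 with an estimated correlation), and with the block 2 rose and 33 fell. The flagella and chemotaxis list by symbol (61 genes) had 2 rises, cheWII at 1.15 ± 0.21 among them, and 3 falls and did not pass (adjusted p = 0.0811). With the block 20 of its members rose and 29 fell. The other flagellar cluster (38 genes) had 0 calls in this and the other comparisons and in the interaction.

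Ribosomal protein genes had a median of -0.47. Of 52, rplQ (bll5375) fell, at -0.73 ± 0.07, 10 fell adjusted over the list alone and 43 fell with the block. The list adjusted p was 3.04e-18, or 0.00224 with an estimated correlation. The respiratory list (median -0.22, adjusted p = 0.000528) and the chaperone list (median -0.17, adjusted p = 0.000663) ranked lower with 0 members called. With the block 4 respiratory genes rose and 24 fell, and 4 chaperone genes rose and 15 fell. Of the 16 nitrogen regulation genes 0 were called, and the list did not pass (adjusted p = 0.997). glnK (blr0612) stood at 0.20 ± 0.86, glnII at -0.03 ± 0.27 and amtB at 0.04 ± 0.34. The 10 nitrate genes had 0 calls, or 2 higher and 3 lower with the block, and the list adjusted p was 0.69. With the block 4 nitrogen regulation genes rose and 4 fell, none of them by 2-fold.

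Other rises were blr5803 at 2.02 ± 0.30, bll3639 at 1.43 ± 0.13, bsr2847 at 1.35 ± 0.29, bll7395 at 1.30 ± 0.44, blr1895 at 1.28 ± 0.40, blr4988 at 1.22 ± 0.18 and blr5556 at 1.21 ± 0.10. Other falls were blr4700 at -1.58 ± 0.26, bll6500 at -1.32 ± 0.22, bll6502 at -1.27 ± 0.54 and fabG (blr4083), of fatty acid synthesis, at -1.06 ± 0.34.

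Of 7836 genes 38 passed, 22 higher and 16 lower, and 3869 passed with the block, 1915 higher and 1954 lower. All 38 were among them with the same sign, and 47 passed the block with at least a 2-fold change. Without replicate 1, 2 or 3 of this comparison 15, 13 and 20 genes passed. Of the 220 genes called in the wild type, 24 were called in the mutant with the same sign.

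Mutant over wild type in low nitrogen asks which genes depend on ntrC when ammonium is absent. blr1448 was lower by the most, at -5.13 ± 0.36 (35-fold, adjusted p = 4.54e-08). It was followed by glnK (blr0612) at -4.13 ± 0.47, glnK (blr0606) at -3.30 ± 0.20, glnII at -3.29 ± 0.23 and amtB at -3.08 ± 0.39. The ferredoxin gene fer3 (bsr1750) was higher in the mutant by 3.81 ± 0.36 (14-fold, adjusted p = 1.26e-06). rhcJ, of type III protein secretion, stood at -2.60 ± 0.12.

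Of the 16 nitrogen regulation genes 5 were lower, the 4 above and glnB at -2.38 ± 0.21. The gene ntrY (blr4489), a sensor kinase encoded next to ntrC, was higher by 0.64 ± 0.12. The list ranked lower (adjusted p = 1.33e-06; adjusted p = 0.0584 with an estimated correlation). With the block 5 members were higher and 6 lower, and the list no longer passed (adjusted p = 0.0885). Of 10 nitrate genes 3 were lower, bll4571 at -2.31 ± 0.25, nrtA at -2.32 ± 0.54 and blr2806 at -1.07 ± 0.27, and 5 adjusted over the list alone (list adjusted p = 1.69e-07). With the block 1 nitrate gene was higher and 6 were lower. Of 6 urease genes ureB was lower, at -1.29 ± 0.26, and the list ranked lower (adjusted p = 0.00097; adjusted p = 0.0645 with an estimated correlation). With the block 4 of the 6 were lower.

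Of 34 nodulation and type III secretion genes 11 were lower and 0 higher, and 13 were lower adjusted over the list alone. nolB (blr1812) stood at -2.20 ± 0.27, nolU (blr1814) at -1.94 ± 0.33 and nodD2 (bll2021), a regulator of nodulation genes, at -1.81 ± 0.42. The list ranked lower (adjusted p = 1.33e-09), at a median of -0.13, and with the block 11 members were higher and 15 lower. The flagellar cluster around fliC had 6 lower genes, and 17 adjusted over the list alone (list adjusted p = 2.48e-21, or 0.00188 with an estimated correlation). In it bll6866 stood at -2.71 ± 0.68, flgD at -1.91 ± 0.44, blr6846 at -1.56 ± 0.25 and bll6847 at -1.39 ± 0.22. With the block 31 of its members were lower and 2 higher. The flagella list by symbol had 3 lower members (list adjusted p = 1.69e-07), with 9 higher and 33 lower with the block.

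Ribosomal protein genes ranked lower (median -0.34, adjusted p = 1.53e-14, or 0.00196 with an estimated correlation). Of them rplM (bll4963) was called at -0.58 ± 0.11, and 47 of 52 were lower with the block. Respiratory genes ranked lower too (median -0.21, adjusted p = 2.17e-07), with nuoN (bll4904), of NADH dehydrogenase, at -0.67 ± 0.06. With the block 5 respiratory genes were higher and 26 lower. The 16 denitrification genes had 0 calls and ranked slightly higher (median 0.21, adjusted p = 0.0496; adjusted p = 0.0745 with an estimated correlation), with 10 higher and 2 lower with the block.

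Other lower genes were bll1862 at -2.89 ± 0.39, bll2012 at -2.50 ± 0.23 and bll1877 at -2.50 ± 0.48. Other higher genes were bll6809 at 1.51 ± 0.38, blr1889 at 1.27 ± 0.24, blr4884 at 1.05 ± 0.13, bll2956 at 0.87 ± 0.38, bll3645 at 0.79 ± 0.04, blr1890 at 0.74 ± 0.14, ribA (blr2615), of riboflavin synthesis, at 0.70 ± 0.13 and blr5556 at 0.69 ± 0.09.

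Of 7836 genes 98 passed, 10 higher and 88 lower in the mutant, and 3940 passed with the block, 2247 higher and 1693 lower. All 98 were among them with the same sign, and 102 passed the block with at least a 2-fold change, 6 higher and 96 lower.

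Mutant over wild type in high nitrogen asks which genes depend on ntrC when ammonium is present. fer3 was again the most increased gene, at 3.61 ± 0.43 (12.2-fold, adjusted p = 6.7e-06). bkdA1 was lowest, at -3.30 ± 0.83 (9.88-fold), with bkdB (blr6333), of the same dehydrogenase, at -2.94 ± 0.65. The genes blr5962, blr5963 and blr5966 stood at -3.29 ± 0.92, -2.69 ± 1.40 and -2.42 ± 0.86, bll6809 at -3.15 ± 0.64 and bll5338 at -2.55 ± 0.55. These genes were also lower in low than in high nitrogen in the wild type.

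Of the 34 nodulation and type III secretion genes 9 were lower and 0 higher, and 11 were lower adjusted over the list alone (list adjusted p = 3.53e-08, median -0.14). rhcJ stood at -2.16 ± 0.17 (n = 2), nolB at -1.88 ± 0.20, nolU at -1.53 ± 0.35 and rhcS (bsr1820) at -1.36 ± 0.31. With the block 9 members were higher and 14 lower. The 3 succinate dehydrogenase genes were lower, sdhA at -1.51 ± 0.33, sdhD at -1.41 ± 0.34 and sdhB at -1.32 ± 0.27, and the respiratory list ranked lower (adjusted p = 0.00359). With the block 2 of its members were higher and 17 lower.

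Chaperone genes ranked higher (median 0.29, adjusted p = 1.2e-08) with 0 of 26 called, 4 higher adjusted over the list alone, and 21 higher and 1 lower with the block. Of the nitrogen regulation genes ntrY was higher, by 0.78 ± 0.20, and glnK (blr0606) and glnB were lower, at -1.31 ± 0.24 and -0.70 ± 0.17. That list did not pass (adjusted p = 0.688), and 5 members were higher and 4 lower with the block. Nitrate genes had 0 calls (adjusted p = 0.795; 2 higher and 1 lower with the block), as had the flagellar cluster around fliC (adjusted p = 0.131; 4 higher and 5 lower with the block) and the flagella list by symbol (adjusted p = 0.188; 6 higher and 10 lower with the block). The ribosomal list (median -0.10) passed with the block alone, at adjusted p = 0.00128 against 0.0872, with 16 members lower (adjusted p = 0.416 with the block and an estimated correlation).

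Other higher genes were bll4376 at 1.62 ± 0.36, dht (blr7615) at 1.36 ± 0.50, blr7172 at 1.28 ± 0.32, bll4168 at 1.27 ± 0.32, blr2506 at 1.19 ± 0.23, bll6154 at 1.17 ± 0.31, blr6144 at 1.01 ± 0.06 and exaA (blr6207) at 0.98 ± 0.46. Other lower genes were bll1804 at -2.38 ± 0.26, bll1846 at -2.17 ± 0.04 and icfA (bll2065) at -2.13 ± 0.59.

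Of 7836 genes 101 passed, 11 higher and 90 lower in the mutant, and 3191 passed with the block, 1700 higher and 1491 lower. All 101 were among them with the same sign, and 113 passed the block with at least a 2-fold change, 15 higher and 98 lower. Without replicate 1 of this comparison 45 genes passed, and without replicate 3 58 did.

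**Figure D2:**
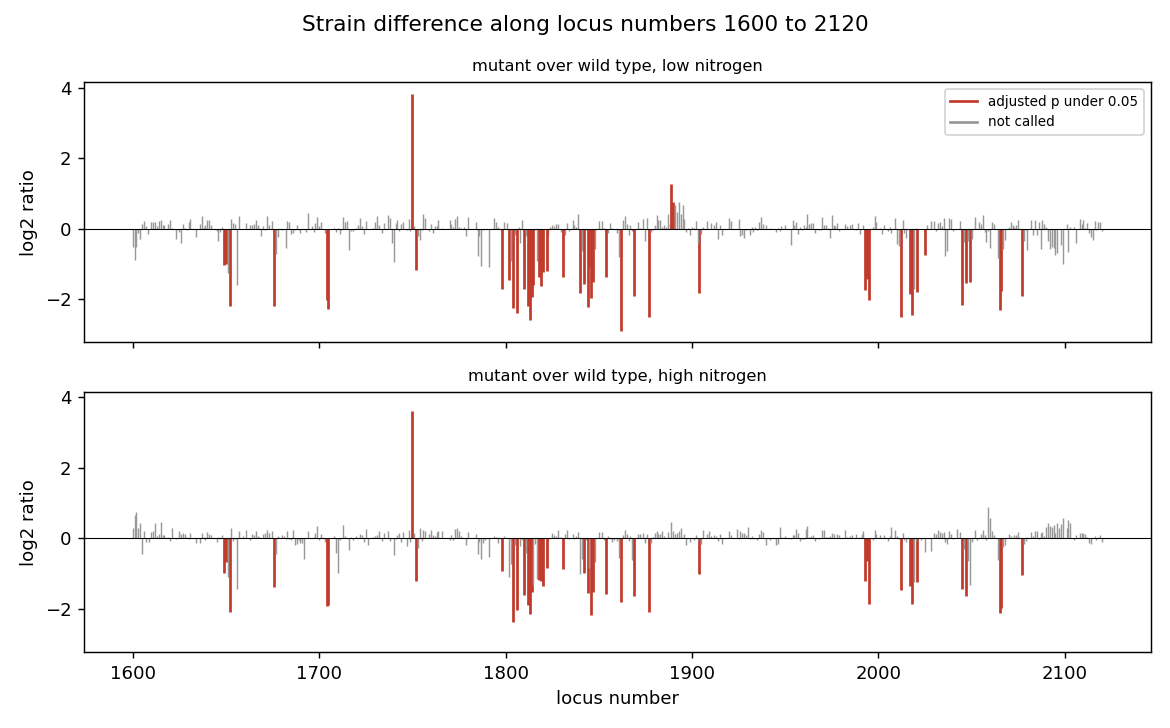
Log2 ratio of mutant over wild type for each gene by locus number across a region that holds many of the nodulation and type III secretion genes, in low and in high nitrogen. Between the first and the last strongly lowered gene 44 genes were called lower in low nitrogen and 38 in high nitrogen, among many genes near 0, and fer3 (bsr1750) stands above 0 in both media.

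The interaction asks whether the nitrogen response differs between the strains. Positive values mean a higher ratio of low over high nitrogen in the mutant, also where this was a smaller fall. Negative values likewise include a fall found in the mutant alone. blr1448 had the lowest value, -5.35 (adjusted p = 2.86e-08), then glnK (blr0612) at -4.35, glnII at -3.71, bll6154 at -2.73, amtB at -2.67, nrtA at -2.50, bll4571 at -2.46, bll7538 at -2.41, bll3763 at -2.32 and bll6866 at -2.30. The highest were bll6809 at 4.72 (adjusted p = 8.82e-06), bkdA1 at 3.91, bkdB at 3.70, blr5962 at 3.28, blr5963 at 2.85, blr5966 at 2.67, bll5338 at 2.54, bsl4167 and bll4510 at 2.45 each and lpdA (blr6334), the dihydrolipoamide dehydrogenase encoded beside bkdB, at 2.34.

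Of the 16 nitrogen regulation genes 5 had a lower response in the mutant, glnK (blr0606) at -2.02 and glnB at -1.70 besides those above, and 6 adjusted over the list alone (list adjusted p = 1.75e-09). With the block 2 were higher and 8 lower. Of the 10 nitrate genes 3 were lower, blr2806 at -1.01 among them, 5 adjusted over the list alone and 7 with the block (list adjusted p = 4.64e-08). ureB was lower, at -1.25, and the urease list ranked lower (adjusted p = 0.000672; adjusted p = 0.0594 with an estimated correlation), with 4 of 6 lower with the block.

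The flagellar cluster around fliC had 6 genes with a lower ratio in the mutant, 10 adjusted over the list alone and 32 with the block, against 2 higher with the block. The list adjusted p was 1.25e-15, or 0.0054 with an estimated correlation. flgD stood at -1.83, bll6847 at -1.39, blr6846 at -1.07 and flgL at -0.82. The flagella list by symbol had 3 lower members (list adjusted p = 0.00027), and 7 higher and 29 lower with the block. rhcC2 was lower, at -0.76, and its nodulation and secretion list ranked lower (adjusted p = 0.00542; adjusted p = 0.0594 with an estimated correlation), with 3 higher and 16 lower with the block. The ribosomal list ranked lower with 0 calls (median -0.26, adjusted p = 4.64e-08), and 41 members were lower with the block.

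Among chaperones groES (bsr7532) was lower, at -1.04, and groEL (blr5626), far from that groES by locus number, at -0.90. The list adjusted p was 4.08e-07, with 2 higher and 14 lower with the block. The array holds other groES and groEL genes, and probes of such paralogous genes can bind each other's cDNA. The succinate dehydrogenase genes were higher, sdhA at 1.33, sdhD at 1.21 and sdhB at 1.11, while the respiratory list had a median of -0.10 and did not pass (adjusted p = 0.116). With the block it ranked lower (adjusted p = 0.0205; adjusted p = 0.266 with an estimated correlation), with 6 members higher and 17 lower.

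Of 7836 genes 132 passed, 59 higher and 73 lower, and 3489 passed with the block, 1833 higher and 1656 lower. All 132 were among them with the same sign, and 120 passed the block with at least a 2-fold change. Deviations shared by same-numbered replicates cancel in the interaction. A gene not called without the block is therefore not shown to respond alike in both strains. Each route to the interaction alone gave 42 genes (nitrogen responses) and 32 genes (strain differences). Of the 220 genes called in the wild type 94 were called in the interaction, and of the 38 called in the mutant 10 were.

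**Figure D3:**
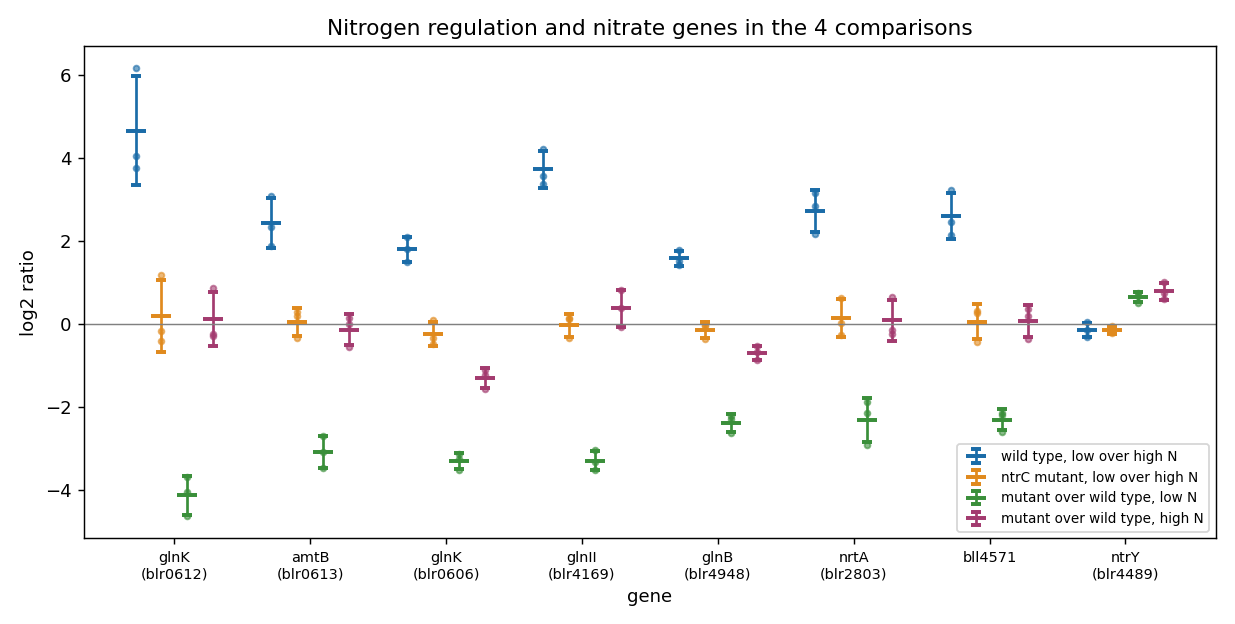
Log2 ratios of nitrogen assimilation genes in the 4 comparisons, with a point for each replicate and the mean with its SD. In low over high nitrogen glnK (blr0612) has a mean of 4.66 in the wild type and 0.20 in the mutant.

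Lists without a called member in any comparison or in the interaction were nitrogenase with fixABCX, microaerobic fix genes, hydrogenase with carbon fixation, exopolysaccharide with polyhydroxybutyrate, and the flagellar cluster away from fliC. In the nitrogen response of the wild type the 19 nitrogenase genes had a median of 0.06 (adjusted p = 0.264; 9 higher and 3 lower with the block) and the 15 microaerobic genes of -0.05 (adjusted p = 0.602; 3 higher and 5 lower with the block). The 39 hydrogenase and carbon fixation genes had a median of 0.04 (adjusted p = 0.542; 12 higher and 6 lower with the block), the 11 exopolysaccharide and polyhydroxybutyrate genes of -0.05 (adjusted p = 0.903; 2 higher and 4 lower with the block), and the 38 genes of that cluster of 0.02 (adjusted p = 0.573; 10 higher and 5 lower with the block). None of the 5 passed as a list in the other comparisons or the interaction, at the preset or at the estimated correlation, with or without the block. The lowest adjusted p was that of the hydrogenase and carbon fixation list in mutant over wild type in low nitrogen. It was 0.0631 with camera, or 0.0647 with the block, where 17 members were higher and 1 lower.

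Of 75 list tests 28 passed at the preset correlation, 19 with an estimated correlation, and 30 with the block at the preset correlation. Without the block the lowest adjusted p was 2.48e-21 at the preset and 0.00188 at the estimated correlation. The list p-values given alone are at the preset correlation. With the block and an estimated correlation 0 passed, the lowest adjusted p being 0.0543.

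The overlap of the calls asks how many genes that respond to nitrogen in the wild type differ between strains in the same medium. Of 106 genes higher in low nitrogen in the wild type and 88 lower in the mutant in low nitrogen, 39 were in both, against 1.19 for independent lists (Fisher's exact test, two-sided, p = 4.61e-52). Without replicate 1 the count was 24. With the block 594 were in both, from much longer lists of 1930 and 1693 genes, so 594 against 39 does not show a stronger overlap. Of 114 genes lower in low nitrogen in the wild type and 90 lower in the mutant in high nitrogen, 43 were in both, against 1.31 (Fisher's exact test, p = 7.5e-58). Of the genes lower in the mutant, 44 were lower in both media, against 1.01 (Fisher's exact test, p = 2.83e-66). The 2 genes higher in both media were fer3 and ntrY. Fisher's test takes the comparisons as independent. Across genes the wild type response and the strain difference in high nitrogen correlated at 0.498, against 0.504 in simulated unchanged genes with shared RNA, at a covariance of 0.0536 against 0.00265. With the strain difference in low nitrogen the correlation was -0.268 against -0.498, at a covariance of -0.0302 against -0.00263. For each of these overlaps, simulated unchanged genes with shared RNA gave a mean of 0 genes in both lists over 20 simulations. Unchanged genes are seldom called in either list, so this mean does not show how much shared RNA adds to an overlap. Whether the comparisons share RNA is not stated, so part of the overlap among changed genes can still come from it.

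The loop closure, tested with limma, had 0 called genes, 0 at an unadjusted p under 0.05, and 116 at an unadjusted p under 0.05 with the block, of which 0 passed the adjustment. Both counts are below the 5% of 7836 genes that chance gives, and deviations shared by the comparisons cancel in the closure, so these tests do not show that the loop closes. Its median absolute deviation over genes was 0.07.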

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

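Tests chosen after the result was seen were the correlation of same-strand neighbours of different prefix, the correlation 24 places apart in the probe list, both tests of the titled direction, and the level of bll1843.

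The nitrogen response differed between the strains for 132 genes by the interaction test. Lower ratios of low over high nitrogen in the mutant were those of blr1448 (-5.35), glnK (blr0612, -4.35), glnII (-3.71), bll6154 (-2.73), amtB (-2.67), nrtA (-2.50), bll4571 (-2.46), bll7538 (-2.41), bll3763 (-2.32) and bll6866 (-2.30). All of these rose in the wild type except bll6866, which stood at 0.03 there and fell in the mutant, at -2.21. Higher ratios in the mutant were those of bll6809 (4.72), bkdA1 (3.91), bkdB (3.70), blr5962 (3.28), blr5963 (2.85), blr5966 (2.67), bll5338 (2.54), bsl4167 (2.45), bll4510 (2.45) and lpdA (2.34). These genes fell in the wild type and were not called in the mutant response. For example, bll6809 stood at -4.43 in the wild type and 0.35 in the mutant. Among 100 reassignments of the strain and medium labels 2 gave as many genes, the real one with 132 and another with 1276. The reassignment with 1276 genes follows the structure of the samples by replicate number, which these reassignments do not keep. Within same-numbered replicates 1 of 32 exchanges, the real one, gave as many as 3489 genes, and the highest of the others gave 0. A share of 1 in 32 is the smallest these exchanges can give. Other exchanges also move real differences into the residual, which lowers their counts. The test therefore does not show how many of the 3489 genes differ.

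One array stood apart from the other 5 of its comparison: the forward array of replicate 1 of the nitrogen response of the mutant had 55 probes without a value, against 19 to 31 on the others. It was the 1 result past Dixon's test among 16 groups of 6 arrays, and chance gives about 1 in 20.

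Same-numbered replicates shared deviations from the group means in all 4 comparisons. A forward array, however, correlated at a median of 0.414 with its own dye swap, and with those of the other numbers at -0.976 to -0.911 for one and 0.25 to 0.402 for the other. A difference in transcript levels between culture batches met its first prediction, since the correlation of neighbouring genes on the same strand exceeded that of opposite-strand neighbours by 0.429. However, 88.9% of same-strand neighbours share a locus tag prefix and so stand next to each other in the probe list, and those of different prefix correlated at 0.0382, which argues against it. Print or plate order is a candidate explanation: list neighbours at least 3 locus numbers apart correlated at 0.324, and genes 24 places apart at 0.313, against -0.319 at 8 places.

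Genes between locus numbers 1651 and 2077, where many but not all of the nodulation and type III secretion genes lie, included 54 of 358 that were lower in the mutant by at least 0.5 in both media. The span was set by its strongly lowered genes, so its share is not a test. Of its measured genes 15.1% were that much lower. This share alone does not exclude a single stretch missing from the mutant, since a missing gene that the wild type does not transcribe also gives a ratio near 0. Loss of the span as a whole is argued against by genes within it that were higher in the mutant. In the span 3 genes were called higher in at least 1 medium, and fer3 stood at 3.81 in low and 3.61 in high nitrogen. Shorter missing stretches were not tested. A lower transcript level of the response regulator gene bll1843 in the mutant was not seen, the lower of its ratios being -0.0527. A probe near background would also give a ratio near 0, so this value does not decide the question. The biological difference of the design, the ntrC mutation, may account for the pattern, as may a further mutation in the single mutant strain; neither was tested.

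The strain ratios ran opposite to the forward titles. If they were deposited as titled, the loop of comparisons would close with a median absolute deviation of 0.35, against 0.07 in the opposite reading. The dye bias of genes would correlate at no more than -0.705 between nitrogen and strain comparisons, where a bias of the probes gives a positive value. Both argue against the titled reading. A joint reversal of all 4 comparisons stays open.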

How the results depend on the processing

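Alternatives chosen after seeing the data were the replicate block for the comparisons, the overlap and the lists, the block with a 2-fold minimum, and the titled direction. In the order wild type response, mutant response, strains in low nitrogen, strains in high nitrogen and interaction (220, 38, 98, 101 and 132 genes), the replicate block gave 4085, 3869, 3940, 3191 and 3489 genes, and all main calls were kept with their sign. It gave 594 shared genes for the overlap in place of 39, from lists of 1930 and 1693 genes, and 0 for the closure. The value behind this is the residual spread, 0.08 with the block and 0.33 without (limma's prior SD). With the block it leaves out the deviations shared by same-numbered replicates. Of named genes the block added 93 calls and lost 0; of lists it added 3 and lost 1, as given beside them, and it changed no other call among them. An estimated correlation ended 9 of 28 list calls. All 24 arrays with a dye term and a random block gave 404, 134, 149, 201 and 265 genes. The loop fit gave 446, 148, 158 and 184 genes for the comparisons, which pool more arrays per contrast. No moderation gave 71 genes for the mutant response. The 2-fold minimum gave 116 genes for the wild type response, 81 for the interaction and 20 for the overlap, fewer by construction. Single routes to the interaction, with fewer arrays, gave 42 and 32. The cause of the other shifts was not tested.

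Turning the strain ratios exchanges the contrasts of the interaction and the closure, up to sign and scale, so their counts change places by construction. In the titled direction the interaction had 0 genes, with or without the block, and the closure 132. There 12 interaction values changed sign: bll5338 -0.0224, bsl4167 -0.00326, sdhB -0.00996, flgL 0.0835, groEL (blr5626) 0.0215, fliC 0.11, blr2806 0.0573, bll6847 0.0318, bll6866 0.0637, bll7538 0.13, amtB 0.27 and bll6154 0.0725. No called gene named here changed sign under any other alternative, and no list passing its test did under centring, an estimated correlation or the block.

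Leaving out 1 replicate at a time gave 76 to 213 genes for the wild type response, 13 to 33 for the mutant response, 73 to 97 and 45 to 99 between strains in low and high nitrogen, 89 to 129 for the interaction, 24 to 34 for the overlap, 25 to 26 list tests passing in place of 28, and 0 to 0 for the closure. Counts moved by over 1.5 times without replicate 1 (76) or 3 (99) of the wild type response, without replicate 1 (15), 2 (13) or 3 (20) of the mutant response, without replicate 1 (45) or 3 (58) of the strains in high nitrogen, and without replicate 1 (24) for the overlap. Fewer replicates lower the counts by construction. Over all replicates left out, values of named genes kept their side of the threshold in 3389 cases, lost the call in 209 and gained it in 2. Counts stayed within 1.5 times under centring, scaling, separate fits, robust variances, a single dye orientation, both filters and the median over probes. The files give no signal over background, so weak probes could not be told from strong ones.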

Other observations

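The level of bll1843 was examined after the result was seen, and the sign patterns were planned.

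Called genes lay next to each other by locus number, and the genes given here beyond the naming rule were chosen after their values were seen. The 3 genes blr1889 to blr1891 rose in low nitrogen in both strains, by 1.20 to 1.98 in the wild type and 1.49 to 2.78 in the mutant. Their interaction did not pass (adjusted p of 0.0608 for blr1889, 0.303 for blr1890 and 0.404 for blr1891), but passed with the block (4.85e-05, 0.00286 and 0.000163). The 4 genes from bkdA1 to lpdA, for the branched-chain 2-oxo acid dehydrogenase, had ratios of -4.80 to -2.10 in low over high nitrogen in the wild type and -3.30 to -1.76 in mutant over wild type in high nitrogen. In wild type low over high nitrogen bll6500, ilvH (bll6501), a subunit of acetolactate synthase, and bll6502 had ratios of -1.99 to -1.35, and pcaF (blr0925), blr0926 and pcaH (blr0927), of aromatic compound breakdown, -0.93 to -0.48. Of 220 genes called in the wild type response 75 had a called neighbour of the same sign within 2 locus numbers. In mutant over wild type the counts were 50 of 98 in low nitrogen and 50 of 101 in high nitrogen. Neighbouring genes on the same strand also shared deviations between replicates (correlation across gene pairs 0.379), so shuffling genes gives no fair comparison for these counts.

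The ferredoxin gene fer3 (bsr1750) lies within the span in which many genes were lower in the mutant, and was higher, by 3.81 ± 0.36 in low and 3.61 ± 0.43 in high nitrogen. Its nitrogen response did not differ detectably between strains (interaction 0.18, adjusted p = 1; adjusted p = 0.0828 with the block). The response regulator gene basR (bll1843), among the secretion genes by locus number, stood at -0.0453 ± 0.236 and -0.0527 ± 0.128 in the 2 media (adjusted p = 1 in each).

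Turning the sign of 1 replicate at a time gave 4 sign patterns per comparison, too few for a share under 0.05. The real signs alone, 1 of 4, gave as many genes. The wild type response had 220 genes against 2 at most in the other patterns, the mutant response 38 against 0, and mutant over wild type 98 against 0 in low nitrogen and 101 against 1 in high nitrogen. A turned sign shrinks the mean of a changed gene and widens its residual, which lowers the other counts by construction.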
